A study of Mus musculus and Mus musculus musculus x Mus musculus castaneus with 52 samples.

How the data were processed

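The series holds 52 samples, of which 32 are RNA sequencing and 20 are chromatin accessibility samples, which are not analysed here. The RNA table has 24 columns, 1 for each line, passage and time. In the LIF-withdrawal experiment each line and time has a library and a technical repeat in the labels (8 repeats) but 1 column in the table, and whether the repeats were combined is not stated. Per the labels, RNA was extracted with TRIzol, libraries were made with a stranded mRNA kit and read single-end on an Illumina instrument. The submitters' processing notes name STAR 2.5.3a, featureCounts and edgeR with the builds GRCm38 and mm10, without giving their roles. The iPSC lines were grown at P7 and P13, the CM lines at P5, and the growth protocol of the chromatin samples names male feeder cells. The F121, Dusp9+/- and CM lines come from crosses of musculus with castaneus mice, and the V6.5 and LV lines are Mus musculus.

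The authors deposited log2 CPM (read counts scaled to library size, on the log2 scale), a unit other than raw counts, for 16687 gene symbols. On the linear scale each column is a floor of 0.183 CPM (-2.45 on the log2 scale) plus whole multiples of 1 step, which is the value of 1 read. Reads were recovered from these steps, and all values (100.0%) lay within 0.01 read of a whole number, with a largest deviation of 0.00034. The offset averaged 2.0 reads. The recovered totals ran from 8309171 to 14245900 reads per library, and the authors' scaling of library size from 0.96 to 1.055. Intervals on reads are exact binomial (Clopper-Pearson) at 95% and cover counting error only. They are given where the lower group of a named gene held 1 to 3 reads in total. Where it held 0 reads the gene is given as listed at 0.

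Gene positions came from a RefSeq annotation of GRCm38.p6, in which 15225 symbols were found directly, 362 through a synonym and 1100 not at all. Of the genes 641 were X-linked, 7 Y-linked and 14933 autosomal, and 6 were unplaced or on several chromosomes. Genes with a mean of at least 1 CPM over the libraries of a fit were tested.

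Log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with the Benjamini-Hochberg adjustment over all genes tested and two-sided tests. The plan had assumed linear values with a pseudocount of 1. Since the table already holds log2 values with an offset, these were fitted unchanged and the pseudocount of 1 became an alternative. The 12 iPSC libraries shared 1 fit with 4 group means (8 residual degrees of freedom). The 6 WT undifferentiated ESC lines shared 1 fit with the experiment as a covariate (3 residual degrees of freedom). The 8 withdrawal libraries were fitted with 6 means of genotype and time (2 residual degrees of freedom), in which the lone F121 and V6.5 libraries are assumed to vary like the clones. The change from 0 h to 24 h was fitted with genotype as a covariate (4 residual degrees of freedom). Differences of changes were tested as interaction terms. X-linked output per library is the median log2 value of X-linked genes minus that of autosomal genes, compared with exact permutation tests. With 3 libraries against 3, groups that do not overlap arise by chance in 10% of genes.

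The 23 gene lists were fixed before the data were examined, as were the comparisons, tests, most alternative settings and the rule for named genes. They are naive pluripotency, core pluripotency, formative and primed, LIF and Stat3 targets, ERK regulators and targets, DNA methylation machinery, germline genes silenced by methylation, imprinted, X-inactivation centre, X escape, X-linked hand list, Y-linked, 2-cell-like, fibroblast and feeder, primitive endoderm, trophoblast, mesendoderm, neuroectoderm, Wnt targets, p53 targets, glycolysis and hypoxia, mitochondrially encoded, and immediate-early and stress. The 2-cell-like list had fewer than 4 tested members and gave no result, so 22 lists were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry. Of 104 camera calls over all comparisons, 2 held with an estimated correlation, both for the Y-linked list. Named genes are the sex and genotype checks (Xist, Dusp9 and 4 Y-linked genes), the 5 largest called increases and decreases among genes whose groups do not overlap and whose higher mean is at least 4 CPM, and up to 4 members of each list that camera called or that held 2 called genes. Nanog was named outside this rule in 2 comparisons (the libraries labelled Dusp9+/- against WT XX at 0 h, and 24 h against 0 h), after its values were seen.

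The fits were tested on simulated data with known 2-fold and 4-fold changes. Reads were drawn at the depth of these libraries, with 1 spread, the median over genes, for all genes of a comparison. The simulation held no line effects and no library that stands apart. Its rates are therefore not the power or error of the real comparisons. In the main comparisons 78.8% of 2-fold and 97% of 4-fold changes were recovered for XX against XY iPSCs, 53.1% and 94.9% for the interaction, 89.5% and 100% for WT ESCs, 78% and 97% for the libraries labelled Dusp9+/- at 0 h, and 65.3% and 86.9% for their difference in response, with false calls at 3.3% to 7.6%. Alternatives changed 1 choice at a time: a pseudocount of 0.1 or 5 on linear CPM, no filter or a filter at 5 CPM, centring on the autosomal median, quantile normalization, robust eBayes, a fold minimum of 2, the spread of the compared groups alone, the line as a block, no term for the experiment, the CM lines alone, an additive model of genotype and time, and each library left out in turn. The pseudocount of 1, limma's voom on recovered reads, a fit without LV21 at P7 and LV22 at P13, a block with the clone numbers crossed at 24 h, and further overlaps of comparisons were chosen after seeing the data. Checks and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.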

Results

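RNA sequencing measured transcript levels in mouse pluripotent stem cells that carry XX, XY or XO sex chromosomes. The induced pluripotent stem cells (iPSCs, cells reprogrammed from somatic cells) comprised 3 female and 3 male lines, each read at passage 7 (P7) and again at passage 13 (P13), when the series names the female lines XO. Embryonic stem cells (ESCs) comprised 2 XX lines (CM1 and CM2) and 2 XY lines (CM3 and CM7) at passage 5, and a withdrawal experiment in which LIF, the cytokine that holds mouse ESCs undifferentiated in serum, was removed for 24 h. The labels describe that experiment as grown without feeder cells. That experiment held the wild-type (WT) XX line F121, the WT XY line V6.5 and 2 clones labelled Dusp9+/-, each at 0 h and 24 h. Dusp9 is an X-linked phosphatase that removes phosphate from the kinase ERK. The 24 libraries held 8309171 to 14245900 recovered reads over 16687 genes, and values are log2 CPM (read counts scaled to library size) with a floor of -2.45 for a gene with 0 reads. Gene differences are limma log2 fold changes ± standard error (SE), and called means a two-sided Benjamini-Hochberg adjusted p under 0.05.

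Dusp9 (chromosome X, 73639389 to 73643514 in GRCm38.p6) was read first in each library labelled Dusp9+/-. At 0 h it stood at 5.96 log2 CPM in the library labelled clone 1 and at 7.43 in the library labelled clone 2, against 6.93 in the single F121 library and 5.91 in the single V6.5 library. At 24 h the order of the clones was the opposite, with 7.71 in the library labelled clone 1 and 6.58 in the library labelled clone 2, against 7.84 in F121 and 6.27 in V6.5. The Dusp9 difference between the libraries labelled Dusp9+/- and WT XX was -0.24 ± 0.66 at 0 h (adjusted p = 0.836) and -0.69 ± 0.66 at 24 h (adjusted p = 0.546), neither of which passed. Without the library labelled clone 1 the 0 h difference was 0.5. The labels do not give the mutated region, so a read of the whole gene does not show which allele was transcribed.

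Sex-chromosome transcripts were read in the same way. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460373 to 103483233), stood at 3.72, 1.66 and 4.33 log2 CPM in the XX iPSC lines LV20, LV21 and LV22 at P7, and at 0.76, -1.85 and 1.55 in the same lines at P13. In the XY iPSC libraries Xist ranged from -2.45 to 0.02. In the XX ESCs it stood at 7.13 in CM1, 6.95 in CM2 and 4.24 in F121 at 0 h, and in the libraries labelled Dusp9+/- at 7.45 and 7.86 at 0 h. The mean of the Y-linked genes was 4.8 to 5.43 in the male iPSC libraries, -0.23 to 0.7 in the female iPSC libraries at P7 and 0.79 to 2.19 in the female libraries at P13.

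The median X-linked gene stood above the median autosomal gene in 2 of the 3 XX iPSC libraries and below it in every XY library. The X-linked minus autosomal median was 0.44 in LV20, -0.16 in LV21 and 0.58 in LV22 at P7, a mean of 0.28 ± 0.39 log2 (SD, n = 3), against -0.51 ± 0.08 (SD, n = 3) in the XY lines. The difference of 0.79 had p = 0.1 in an exact two-sided permutation test, the smallest value that 3 against 3 allows. At P13 the lines named XO had a mean of -0.42 ± 0.24 (SD, n = 3) and the XY lines -0.46 ± 0.08 (SD, n = 3), a difference of 0.04 (exact permutation p = 1), which became -0.1 without LV22. The change from P7 to P13 averaged -0.71 in the female lines (exact permutation p = 0.2) and 0.05 in the male lines (exact permutation p = 0.5). Both tests permuted the libraries as unpaired, although the same lines were read at both passages. From P7 to P13 the value moved by -0.97 in LV20, -0.43 in LV21 and -0.72 in LV22, and by 0.08, 0.12 and -0.04 in LV4, LV8 and LV16. The mean change of the female lines minus that of the male lines was -0.76 (exact permutation p = 0.1, the smallest possible with 6 lines). In WT ESCs the XX lines had 0.21 ± 0.06 and the XY lines -0.57 ± 0.18 (SD, n = 3 each), a difference of 0.78 (exact permutation p = 0.1), with 0.7 within the CM lines and 0.93 within the withdrawal experiment, where each sex was 1 line.

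**Figure D1:**
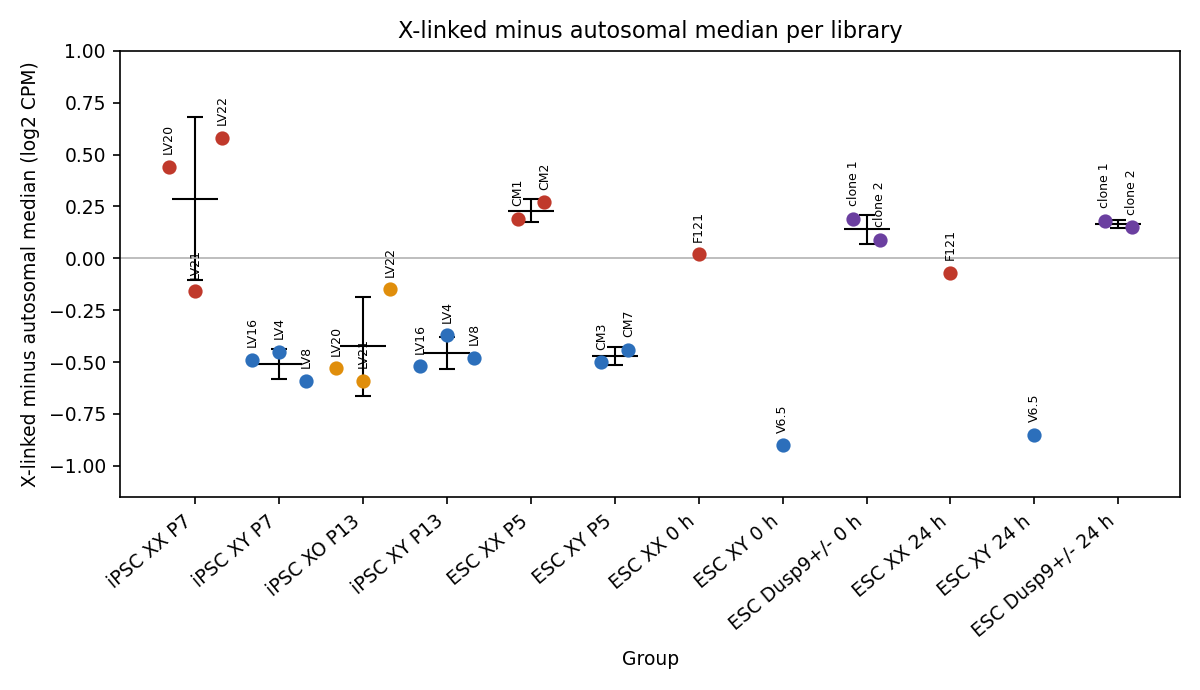
Median log2 CPM of X-linked genes minus that of autosomal genes in each of the 24 libraries, by group; points are libraries (red XX, blue XY, orange XO, purple Dusp9+/-), horizontal bars are means and error bars the SD where a group has more than 1 library. LV20 and LV22 at P7 sit at 0.44 and 0.58 and LV21 at -0.16, while the 6 XY iPSC libraries sit between -0.59 and -0.37; ESC libraries at 0 h and 24 h use the genes tested in the withdrawal experiment.

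The comparison of XX with XY iPSCs at P7 asks how lines labelled XX differ from lines labelled XY. Pramel6 and Pramel7, neighbouring genes of a family expressed in germ cells and early embryos, were higher in XX (n = 3 against 3), with 404 reads against 3 for Pramel6, a ratio of 122 (95% counting interval 41.5 to 594), and 409 against 3 for Pramel7, a ratio of 124 (42.0 to 602). The X-linked Polycomb gene Scml2 (chromosome X, 161082525 to 161258218) was 16.5-fold higher, the naive pluripotency factor Tbx3 3.95-fold higher and the germ-cell RNA-binding gene Dazl 6.58-fold higher. Of 13978 genes tested, 668 were called, 427 higher and 241 lower in XX. All 165 called X-linked genes were higher, out of 509 tested (32.4%, against 3.7% of autosomal genes, Fisher exact p = 3.56e-95 across genes), and the X-linked median change was 0.62 (quartiles 0.39 and 0.96).

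Among the largest increases in XX iPSCs were also Xist (4.85 ± 0.84) and Obox6 (4.04 ± 0.67), an oocyte-type homeobox gene. The Y-linked translation factor Eif2s3y was 61.1-fold lower, the demethylases Kdm5d and Uty 29.6-fold and 28.0-fold lower, and the RNA helicase Ddx3y 15.4-fold lower. Muc3a, a membrane mucin, was 4.09-fold lower. Of the 22 naive pluripotency genes 6 were called, all higher, and 8 were when adjusted over the list alone. They included Klf5 (0.74 ± 0.15), a factor that sustains self-renewal, the imprint-protecting zinc-finger gene Zfp57 (0.55 ± 0.12), the kinase coactivator Tcl1 (1.35 ± 0.35) and the germ-cell regulator Prdm14 (1.24 ± 0.33). The core factors Pou5f1 (0.34 ± 0.08) and Dppa2 (0.98 ± 0.22) were also higher. Of 25 germline genes whose promoters are silenced by DNA methylation 7 were called higher (15 higher and 1 lower adjusted over the list alone), such as the meiotic genes Syce1 (2.2 ± 0.35) and Sycp1 (1.75 ± 0.39) and the X-linked transcription factor subunit Taf7l (2.3 ± 0.45). By camera both lists were higher as sets, with adjusted p = 1.41e-05 and 3.22e-07, but each had adjusted p = 0.378 with an estimated correlation.

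Of 54 X-linked genes named beforehand (the hand list) 20 were called, all higher, and 41 adjusted over the list alone, among them Porcn (1.54 ± 0.27), which acylates Wnt proteins, Ndufa1 (1.19 ± 0.2), a respiratory chain subunit, and the cohesin gene Smc1a (0.49 ± 0.09). Genes known to escape X inactivation were higher in 4 of 11 cases (6 adjusted over the list alone), including the demethylases Kdm6a (0.74 ± 0.16) and Kdm5c (0.5 ± 0.12) and the helicase Ddx3x (0.44 ± 0.12). In the X-inactivation centre 3 of 7 genes were higher (3 adjusted over the list alone), Xist, its antisense Tsix (1.4 ± 0.37) and the brain-expressed Chic1 (0.94 ± 0.18). Dusp9 was 2.02-fold higher (1.01 ± 0.26, adjusted p = 0.0416), a call that was lost without LV22 (adjusted p = 0.193), LV20 (0.166), LV4 (0.106), LV16 (0.117) or LV8 (0.121), the range over its 19 alternatives reaching up to 0.193. Mitochondrially encoded genes were higher in 5 of 7 cases (6 adjusted over the list alone), such as mt-Nd1 (0.71 ± 0.12) and mt-Cytb (0.74 ± 0.13), and 4 of 18 glycolysis and hypoxia genes were lower (6 adjusted over the list alone), such as Tpi1 (-0.64 ± 0.13) and Pdk1 (-0.78 ± 0.17). Camera called the hand, escape, X-inactivation centre, mitochondrial and glycolysis lists (adjusted p = 3.34e-20, 2.05e-05, 0.0168, 2.53e-07 and 1.03e-05), with adjusted p = 0.239, 0.239, 0.217, 0.217 and 0.378 with an estimated correlation. All 5 Y-linked genes were lower (5 adjusted over the list alone, camera adjusted p = 7.57e-15), a call that held with an estimated correlation (adjusted p = 0.0153). Imprinted genes went both ways, with Plagl1 (1.14 ± 0.28) higher and Igf2 (-1.28 ± 0.26) and Slc22a18 (-1.8 ± 0.48) lower. The Xist call was lost without LV22 (4.3, adjusted p = 0.0661) or LV8 (4.43, adjusted p = 0.0569). The count of called genes rested on each library, since it was 1727 without LV21, 44 without LV22, 123 without LV20, 285 without LV4, 209 without LV16 and 59 without LV8. Of the 37 called genes named here 9 kept their calls whichever library was left out (Pramel6, Pramel7, Scml2, Tbx3, Dazl and the 4 named Y-linked genes), while 28 lost theirs without LV22, 24 without LV8, 18 without LV20, 15 without LV16 and 12 without LV4. The count was also 428 with the spread taken from these 6 libraries alone and 1818 without LV21 at P7 and LV22 at P13.

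At P13 the lines named XO were compared with the XY lines to ask what differs under that label. Only Y-linked genes were called: Uty was 21.2-fold, Eif2s3y 16.0-fold and Ddx3y 6.4-fold lower in XO (n = 3 against 3), and the ubiquitin-activating gene Uba1y had 1 read against 114, a ratio of 96.8 (95% counting interval 17.0 to 3860.0). These 4 were the only called genes of 13978. An unadjusted p under 0.05 was found for 376 genes, a share below the 0.05 that chance alone gives on average. Kdm5d (-2.7 ± 0.58, adjusted p = 0.547), Xist (0.64 ± 0.84, adjusted p = 1) and Dusp9 (0.27 ± 0.26, adjusted p = 1) did not pass, and the Xist value was -0.06 without LV22. As a set the 5 Y-linked genes were lower (5 adjusted over the list alone, camera adjusted p = 5.68e-33), also with an estimated correlation (adjusted p = 0.000885). Of the 509 X-linked genes 0 were called by limma, with a median of 0.08 (quartiles -0.04 and 0.25), and voom on recovered reads called 4 genes in all. None of the 22 naive genes (median 0.19), 25 germline genes (median 0.61) or 54 genes of the X-linked hand list (median 0.07) was called, also adjusted over the list alone. Their camera calls (adjusted p = 8.02e-06, 2.55e-08 and 0.00613) had adjusted p = 0.659, 0.659 and 0.791 with an estimated correlation.

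In the female lines P13 was compared with P7 to ask what changes as the series' label goes from XX to XO. X-linked genes moved down: 152 of 509 fell and 3 rose, against 595 autosomal genes that rose and 487 that fell, and the X-linked median change was -0.57 (quartiles -0.87 and -0.27, n = 3 against 3). Scml2 fell 8.01-fold (-3.0 ± 0.6), Xist 8.46-fold (-3.08 ± 0.84) and Dusp9 2.44-fold (-1.29 ± 0.26), a Dusp9 change whose difference from that of the male lines did not pass (adjusted p = 0.581). Among the largest increases were Irf7, a transcription factor of the interferon response, 54.0-fold (5.75 log2, with 2.08 at a pseudocount of 5 and 6.57 by voom), Ifi44 23.8-fold, Fcgr1, an immunoglobulin receptor, 17.9-fold and Ifit1 13.9-fold higher at P13. Ifit3 had 236 reads at P13 against 2 at P7, a ratio of 127 (95% counting interval 34.9 to 1060.0). The total was 1258 called genes, 604 higher and 654 lower.

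Other large decreases in the female lines were the mesendoderm factor Lhx1 (-3.48 ± 0.98), the channel gene Pkd2l1 (-3.17 ± 0.76) and the X-linked receptor Gpr50 (-2.81 ± 0.74). On the X-linked hand list 20 of 54 fell (30 adjusted over the list alone), such as the chromatin gene Rbbp7 (-0.6 ± 0.09), the copper transporter Atp7a (-0.9 ± 0.16) and Smc1a (-0.46 ± 0.09). The X-inactivation centre had 3 of 7 lower (5 adjusted over the list alone), with the noncoding Ftx at -0.99 ± 0.22. The escape genes had 3 of 11 lower (6 adjusted over the list alone), with Mid1 at -0.76 ± 0.19. Of 18 immediate-early and stress genes 11 fell and 1 rose (13 and 2 adjusted over the list alone), with Jun 5.12-fold, Fosb 5.18-fold, Fos 5.25-fold and Atf3 3.8-fold lower. Of 15 p53 targets 7 fell (11 adjusted over the list alone), among them Btg2 (-1.36 ± 0.23) and Cdkn1a (-0.73 ± 0.14). Of 25 fibroblast and feeder genes 9 rose and none fell (18 adjusted over the list alone), led by the collagens Col3a1 (4.29-fold) and Col1a1 (3.03-fold). These genes are also expressed in fibroblast feeder cells, and the growth protocol of the chromatin samples names male feeders. Y-linked Ddx3y (1.17 ± 0.31), Eif2s3y (1.69 ± 0.4) and Kdm5d (2.08 ± 0.58) rose as well. The naive list was split, with Klf4 (-0.77 ± 0.12) and Nanog (-0.94 ± 0.23) down and the lysosomal gene Manba (0.76 ± 0.15) and Gbx2 (1.31 ± 0.32) up. The DNA methyltransferase Dnmt3a rose by 0.83 ± 0.2 and its cofactor Dnmt3l by 1.03 ± 0.22, while the demethylase Tet3 fell by 0.9 and Uhrf2 by 0.71. Of these sets the hand list, fibroblast, immediate-early and p53 lists passed camera (adjusted p = 2.02e-11, 7.99e-09, 1.88e-07 and 0.000128), with adjusted p = 0.348, 0.366, 0.258 and 0.348 with an estimated correlation. The count was 2079 without LV21 at P7, 393 without LV22 at P7, 174 without LV20 at P7, 304 without LV20 at P13 and 702 without LV22 at P13, and 436 with the spread from these 6 libraries alone. Of the 35 called genes named here 17 kept their calls whichever library was left out, among them Fos, Jun and Col3a1, while 15 lost theirs without LV20 at P7, 15 without LV20 at P13, 12 without LV22 at P7, 7 without LV21 at P13, 6 without LV22 at P13 and 2 without LV21 at P7. By voom the calls of Irf7, Ifi44, Ifit1 and Ifit3 were lost (adjusted p = 0.113, 0.126, 0.0619 and 0.074), and 7 of the 35 kept theirs in every alternative. The Xist call was lost without LV22 at P7 (-2.54, adjusted p = 0.138), LV20 at P7 (-2.84, 0.134), LV20 at P13 (-3.38, 0.0769) or LV21 at P13 (-2.08, 0.0992), and the Dusp9 call without LV22 at P7 (-1.16, 0.0526), LV20 at P7 (-1.01, 0.0644) or LV20 at P13 (-1.18, 0.0573).

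The male lines at P13 were compared with P7 to ask what changed between passages where the label stays XY. Il1rl1, a receptor for the cytokine IL-33, rose 15.8-fold, Siglec1, a macrophage lectin, 18.6-fold, Ifi44 21.2-fold, Irf7 15.9-fold and Ifit3 13.8-fold (n = 3 against 3). For Irf7, Ifi44 and Ifit3 these means rest mainly on LV4 and LV8. Irf7 went from -0.66 to 4.88 log2 CPM in LV4 and from -1.25 to 4.6 in LV8 but from -0.28 to 0.31 in LV16, and Ifi44 from -0.45 to 0.23 in LV16. Without LV16 at P13 the log2 changes were 5.47 for Irf7, 5.72 for Ifi44, 5.34 for Ifit3 and 5.05 for Siglec1, against 3.19 for Irf7 and 2.93 for Ifit3 without LV4 at P13 and 3.33 and 3.1 without LV8 at P13. By voom the calls of Irf7, Ifi44, Ifit3 and Siglec1 were lost (adjusted p = 0.263, 0.127, 0.249 and 0.059). The mesenchymal factor Prrx1 rose 4.8-fold, Col3a1 5.04-fold and the matrix gene Dcn 4.16-fold. The BMP antagonist Nog fell 7.24-fold, the keratin Krt19 6.83-fold, the myosin Myh7 5.68-fold, the Wnt inhibitor Rnf43 5.52-fold and Fos 5.14-fold. In total 1823 genes were called, 1010 higher and 813 lower, with 21 X-linked genes higher and 15 lower (7.1% of X-linked against 13.6% of autosomal genes) and an X-linked median of 0.

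Of 25 fibroblast and feeder genes 17 rose and none fell (21 adjusted over the list alone), including Thbs2 (1.66 ± 0.26). Of 18 glycolysis and hypoxia genes 10 fell (11 adjusted over the list alone), such as the glucose transporters Slc2a3 (-1.01 ± 0.16) and Slc2a1 (-0.87 ± 0.16). Mitochondrially encoded genes rose in 5 of 7 cases (6 adjusted over the list alone), with mt-Cytb at 1.1 ± 0.13, and 7 of 18 immediate-early and stress genes fell while 2 rose (10 and 2 adjusted over the list alone), with Jun at -1.98 ± 0.26. Core pluripotency genes rose in 4 of 12 cases (5 adjusted over the list alone), with Dppa2 at 1.4 ± 0.22 and Pou5f1 at 0.44 ± 0.08. Foxd3, a regulator of the exit from naive pluripotency, rose 5.3-fold and the FGF target Etv4 2.31-fold. The LIF target Socs3 fell by 1.31 ± 0.18 on the log2 scale, while Spp1, a secreted phosphoprotein on the same list, rose by 1.19 ± 0.22. Camera called the fibroblast, glycolysis, mitochondrial, immediate-early and core lists (adjusted p = 2.73e-13, 3.22e-07, 6.04e-07, 0.00351 and 0.00216), and with an estimated correlation their adjusted p = 0.384, 0.384, 0.375, 0.481 and 0.375. Dusp9 did not pass (-0.55 ± 0.26, adjusted p = 0.183), but was called with the spread of these 6 libraries alone (adjusted p = 0.00843) and without LV21 at P7 and LV22 at P13 (adjusted p = 0.00526). Without LV4 at P13 the count was 429, without LV8 at P13 752, without LV16 at P7 1018 and without LV8 at P7 505. Of the 24 called genes named here only Irf7, Ifit3, Nog and Myh7 lost a call with 1 library left out, 4 of them without LV8 at P7, 3 without LV4 at P13, 2 without LV8 at P13 and 1 each without LV4 at P7, LV16 at P7 and LV16 at P13, and 16 of the 24 kept theirs in every alternative.

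**Figure D2:**
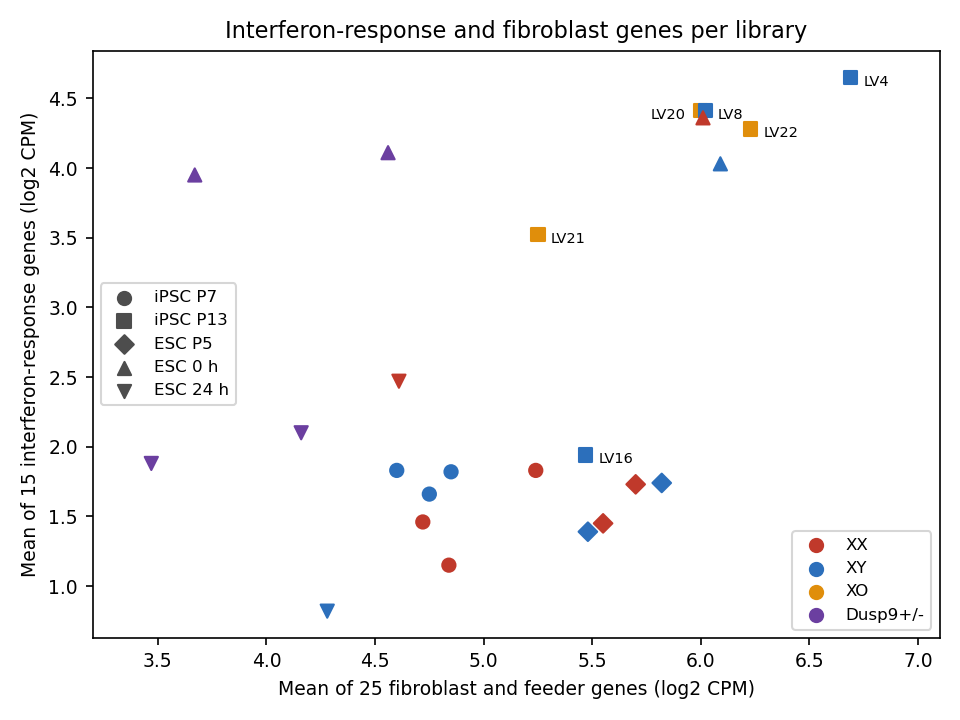
Mean log2 CPM of 15 interferon-response genes, a list chosen after the values were seen, against the mean of the fibroblast and feeder genes, each point 1 library, with colour and marker for its group as in the legend. At P13 the interferon mean was 4.65 in LV4, 4.41 in LV8, 4.41 in LV20, 4.28 in LV22 and 3.52 in LV21 but 1.94 in LV16, against 1.15 to 1.83 in the P7 libraries.

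Whether passage changed female and male lines differently was tested directly as an interaction. By limma 0 of 13978 genes passed, with 1242 at an unadjusted p under 0.05 and 0 by voom on recovered reads. The smallest adjusted p was 0.434. Xist moved by -4.21 ± 1.18 log2 in female relative to male lines (adjusted p = 0.45), Eif2s3y by 1.93 ± 0.56 (adjusted p = 0.464) and Dusp9 by -0.74 ± 0.37 (adjusted p = 0.581). The X-linked median of the interaction was -0.57 (quartiles -0.89 and -0.33) and 6.7% of the 509 X-linked genes were above 0, against an autosomal median of 0.01. With the line as a block 11 genes passed, 2 higher and 9 lower. Without LV21 at P7 145 passed, among them Xist (-4.99, adjusted p = 0.0477) and Dusp9 (-1.14, adjusted p = 0.0404), and without both LV21 at P7 and LV22 at P13 364 passed, 112 higher and 252 lower.

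WT XX and XY ESCs were compared to ask how embryo-derived lines labelled XX differ from those labelled XY. F121 comes from a cross with castaneus mice and V6.5 does not, so sex and strain cannot be separated in that pair. The CM lines of both sexes come from such crosses. An XY line carries a single X chromosome, so the strain of X-linked alleles cannot be separated from sex in the CM lines either. The X-linked deubiquitinase Usp26 (chromosome X, 51752667 to 51801233) was 18.9-fold higher in XX (4.24 ± 0.13), the X-linked peptidase Xpnpep2 20.7-fold and Xist 83.8-fold (6.39 ± 0.57, n = 3 against 3). Klhl13 (chromosome X, 23219271 to 23365161), an adaptor of a ubiquitin ligase, was 4.7-fold higher and Dusp9 2.14-fold higher (1.1 ± 0.13). Nanog was 2.0-fold and Prdm14 2.52-fold higher, while the de novo methyltransferases Dnmt3b and Dnmt3a were 2.29-fold and 1.66-fold lower. Of 14193 genes tested 1020 were called, 691 higher and 329 lower, and all 250 called X-linked genes were higher, out of 533 (46.9%, against 5.8% of autosomal genes, Fisher exact p = 5.79e-146 across genes). The X-linked median was 0.71 (quartiles 0.37 and 1.0).

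Rps4x-ps, a pseudogene whose sequence resembles that of X-linked Rps4x, was listed at 0 reads in the 3 XY libraries and at 5.97, 6.03 and 5.96 log2 CPM in CM1, CM2 and F121. Whether strain or reads shared with Rps4x play a part was not tested. The tubulin gene Tuba3b was 4.82 ± 0.78 higher in XX. Among Y-linked genes Uty was 18.3-fold, Eif2s3y 9.62-fold and Ddx3y 8.87-fold lower in XX, while Kdm5d did not pass (-0.01 ± 0.41, adjusted p = 0.99). The brain proteoglycan Ncan was 6.54-fold lower and the placental gene Plac8 5.14-fold lower. Naive genes were higher in 8 of 22 cases (10 higher and 1 lower adjusted over the list alone), including Tbx3 (1.14 ± 0.16), the Pou5f1 target Fbxo15 (0.89 ± 0.1) and Klf5 (0.41 ± 0.08). Genes of the formative and primed states were lower in 5 of 19 cases (5 adjusted over the list alone), such as Etv4 (-1.25 ± 0.11) and the RNA-binding Lin28b (-0.66 ± 0.11). The ERK list was split, with 3 of 22 higher and 4 lower (3 and 7 adjusted over the list alone). The inhibitor Spred1 (-0.66 ± 0.09) was among the lower ones. Germline genes were higher in 9 of 25 cases and lower in 1 (14 and 2 adjusted over the list alone), with the meiotic genes Hormad1 (2.37 ± 0.15) and Smc1b (2.92 ± 0.27) and the small-RNA pathway gene Fkbp6 (2.17 ± 0.22). Imprinted genes were higher in 6 of 37 cases and lower in 4 (7 and 4 adjusted over the list alone), with Peg12 (2.05 ± 0.25) and Plagl1 (1.78 ± 0.18) up and Phlda2 (-2.01 ± 0.25) down. On the X-linked hand list 35 of 55 were higher (43 adjusted over the list alone), among them the sterol isomerase Ebp (1.41 ± 0.11), Wdr45 (1.77 ± 0.11), which acts in autophagy, and the ubiquitin ligase Cul4b (0.75 ± 0.06). Of 13 Wnt targets 1 was higher and 2 were lower (2 and 3 adjusted over the list alone), with Axin2 at -1.31 ± 0.2, and 4 of 15 p53 targets were higher (6 adjusted over the list alone), with Mdm2 at 0.42 ± 0.08. The hand list, naive and germline lists passed camera (adjusted p = 1.06e-26, 5.52e-05 and 4.78e-07), with adjusted p = 0.241, 0.419 and 0.402 with an estimated correlation. The count was 208 without CM2, 265 without CM1, 557 without CM3, 1573 without F121 and 1682 without V6.5, and of the 33 called genes named here 8 lost their calls without CM2, 6 without CM1 and 1 without CM3, and 15 kept theirs in every alternative. With F121 or V6.5 left out, the term for the experiment takes up the other, so these fits estimate sex from the CM lines. They are not separate from the fit of the CM lines alone, which gave 1690. A fit with no term for the experiment gave 149, and in it the Dusp9 call was lost (1.1, adjusted p = 0.265, the highest over its 18 alternatives).

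At 0 h the libraries labelled Dusp9+/- were compared with the WT XX line to ask what changes when 1 copy of Dusp9 is mutated in XX cells. Hand1, a trophoblast and heart transcription factor (chromosome 11, 57828713 to 57832147), was 12.0-fold higher, Krt18 11.7-fold and Xist 10.6-fold (n = 2 against 1). Xist was low in F121 at 0 h (4.24 log2 CPM), against 6.41 in F121 at 24 h and 7.13 and 6.95 in CM1 and CM2. The libraries labelled Dusp9+/- (7.45 and 7.86) lay nearer to CM1 and CM2, so the Xist difference cannot be assigned to the genotype. The ERK-induced phosphatases Dusp6 and Dusp4 were 2.49-fold and 3.06-fold higher and the early response genes Jun 6.7-fold and Fosb 5.02-fold higher. The matrix gene Postn was 27.4-fold, Dazl 4.43-fold and the methylcytosine dioxygenase Tet2 2.21-fold lower. The interferon-inducible Ifi202b had 3 reads against 91 in WT XX, a ratio of 54.8 (95% counting interval 18.2 to 270.0). Of 14335 genes 1277 were called, 689 higher and 588 lower. The larger side depended on the scaling, with 625 higher and 775 lower after centring on the autosomal median. After quantile normalization 552 were higher and 427 lower. Among 555 X-linked genes 63 were higher and 13 lower, with a median of 0.23 (quartiles -0.08 and 0.54).

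Further large differences at 0 h were the carbonic anhydrase Car4 (3.87 ± 0.19) on the higher side and Col3a1 (-3.77 ± 0.72), the arginase Arg1 (-3.72 ± 0.58) and Dcn (-3.72 ± 0.5) on the lower side. Naive genes were lower in 9 of 22 cases and none was higher (12 adjusted over the list alone), such as Nr5a2 (-1.4 ± 0.13), Tbx3 (-1.05 ± 0.14), Fbxo15 (-1.08 ± 0.11) and Nanog (-0.81 ± 0.12). Formative and primed genes went both ways, with 5 of 19 higher and 3 lower (7 and 5 adjusted over the list alone). Fgf5, a marker of the primed state, was 4.99-fold and Dnmt3b 1.65-fold higher, while Etv4 was 1.68-fold lower. The ERK list had 8 of 22 higher and 1 lower (9 and 4 adjusted over the list alone), Egr1 being 2.67-fold and Ier3 3.66-fold higher. Germline genes were lower in 11 of 26 cases and higher in 1 (14 and 1 adjusted over the list alone), with Stk31 (-1.38 ± 0.17), Fkbp6 (-1.46 ± 0.18) and Piwil2 (-1.16 ± 0.14). Trophoblast genes were higher in 4 of 11 cases (9 adjusted over the list alone), with Krt7 (2.97 ± 0.47) and Krt8 (3.05 ± 0.65). Imprinted genes were higher in 5 of 36 cases (7 higher and 2 lower adjusted over the list alone), led by H19 (2.59 ± 0.19) and Mkrn3 (1.52 ± 0.24). Fibroblast and feeder genes were lower in 8 of 24 cases (19 adjusted over the list alone), such as Fbn1 (-2.16 ± 0.24). The mean of that list was 3.67 and 4.56 log2 CPM in the libraries labelled clone 1 and clone 2, 6.01 in F121 and 6.09 in V6.5. The Y-linked mean was 0.76 and 1.45 under the labels clone 1 and clone 2 and 2.03 in F121. Whether male fibroblast RNA in F121 accounts for lower matrix genes was not tested. Chromosome 12 genes, higher in the library labelled clone 1, had a median difference of 0.3, with 21 of 465 higher and 4 lower. The primitive endoderm list had 1 of 12 higher, Lrp2 (1.86 ± 0.25), and 2 lower, with Lama1 at -1.31 ± 0.11 (2 and 3 adjusted over the list alone). Of 9 mesendoderm genes 2 were higher, Wnt8a (2.52 ± 0.46) and Wnt3, with 58 reads against 3, a ratio of 10.7 (95% counting interval 3.49 to 53.4), and 3 were higher and 2 lower adjusted over the list alone. The naive, germline, trophoblast and fibroblast lists passed camera (adjusted p = 9.96e-07, 1.24e-06, 1.56e-05 and 1.04e-08), with adjusted p = 0.464, 0.587, 0.464 and 0.632 with an estimated correlation. WT XX is 1 library here, assumed to vary like the clones, so the line and the genotype cannot be separated. Leaving out a clone at 0 h left 1 library against 1, with the spread from the 24 h clones alone. Calls kept in such a fit do not show that the clones agree. Of the 36 called genes named here 20 kept their calls in every alternative. An additive model of genotype and time gives 1 genotype difference over both times, not a value for 0 h. In it 12 of the 36 lost their calls, among them Fgf5 (0.67, adjusted p = 0.508), Tbx3 (-0.34, adjusted p = 0.514) and Egr1 (0.41, adjusted p = 0.526). Krt8 lost its call in 5 of 13 alternatives and Wnt3 in 5 of 12. Without the library labelled clone 2 the count was 1953, and without a filter on low genes 759.

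**Figure D3:**
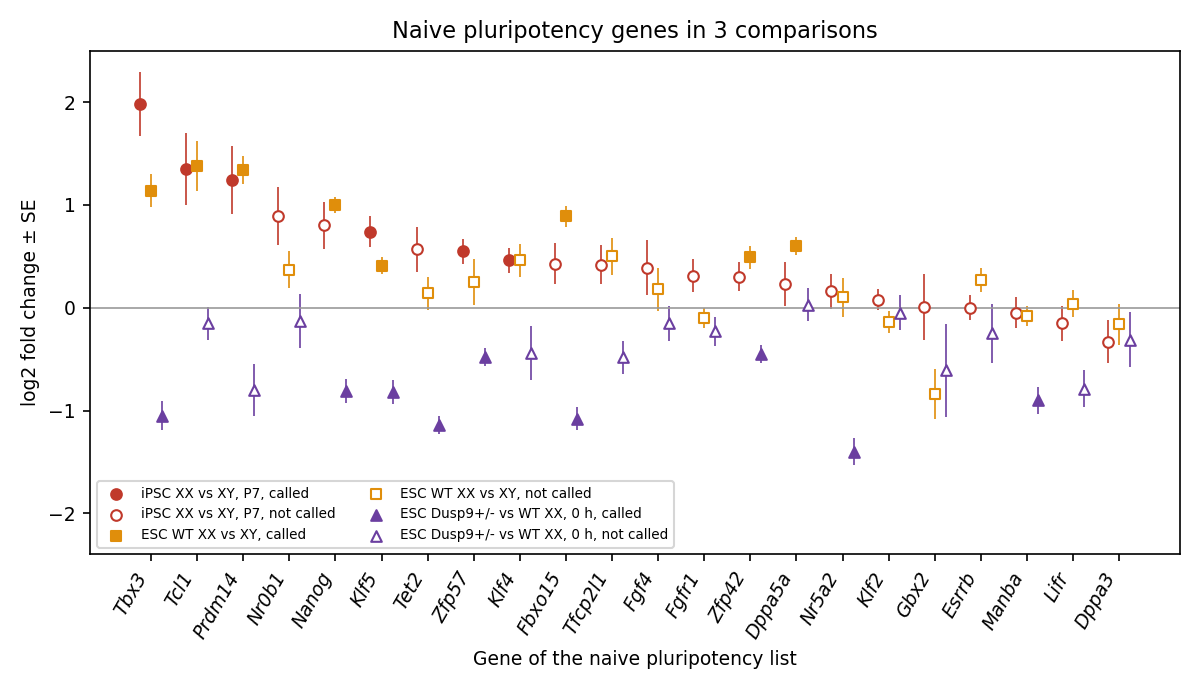
Log2 fold change ± SE of the 22 naive pluripotency genes in XX against XY iPSCs at P7 (circles), WT XX against XY ESCs (squares) and libraries labelled Dusp9+/- against WT XX ESCs at 0 h (triangles); filled symbols are called genes. The called genes are higher in XX in both XX against XY comparisons (6 and 8 genes), and the 9 called in the libraries labelled Dusp9+/- are lower than in WT XX. The F121 library at 0 h is in both ESC comparisons, on opposite sides, so their opposite signs are not independent.

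At 24 h the libraries labelled Dusp9+/- were again compared with WT XX. Hand1 was 17.7-fold, Krt8 23.4-fold, Krt7 15.3-fold, Gata2 11.9-fold and Wnt7b 7.61-fold higher (n = 2 against 1), and 8 of 11 trophoblast genes were higher (10 adjusted over the list alone). That list had a camera adjusted p = 4.06e-10, and adjusted p = 0.618 with an estimated correlation. The keratin pseudogene Krt8-ps (4.85 ± 0.55), whose reads can be shared with Krt8, and the choline enzyme Chdh (3.87 ± 0.63) were among the largest increases. The germline gene Asz1 (-3.22 ± 0.41), Pkd2l1 (-3.02 ± 0.41), the inflammasome-like Nlrp4c (-2.58 ± 0.35), the peptidase Dpp4 (-2.55 ± 0.2) and the phospholipase Pld1 (-2.55 ± 0.26) were among the lowest. The imprinted genes H19 (10.5-fold), Igf2 (5.63-fold) and Sfmbt2 (2.66-fold) were higher, with 4 of 36 higher and 1 lower (12 and 2 adjusted over the list alone). Formative genes were lower in 3 of 19 cases (1 higher and 7 lower adjusted over the list alone), such as Zic2 (-0.88 ± 0.12). The total was 366, 225 higher and 141 lower, and it depended on each clone, with 104 without the library labelled clone 1 and 1 without clone 2. Of the 16 called genes named here 4 lost their calls without clone 1 and 15 without clone 2, all but H19. The Hand1 call was lost without clone 2 (3.82, adjusted p = 0.058), without the filter on low genes (4.15, adjusted p = 0.0682) and by voom (4.34, adjusted p = 0.0545). Leaving out a clone left 1 library against 1, with the spread from the 0 h clones alone. The count of called genes was also 16 by voom, 0 by limma without a filter on low genes (3875 at an unadjusted p under 0.05), 148 after quantile normalization and 178 with a pseudocount of 5.

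Against the WT XY line at 0 h the libraries labelled Dusp9+/- differed in 4992 genes, 2699 higher and 2293 lower. The larger side depended on the processing. Centring on the autosomal median gave 2459 higher and 2557 lower, and quantile normalization 1935 and 2061, whereas robust eBayes gave 2712 and 2332. Klhl13 was 8.91-fold, Fgf5 24.7-fold, H19 22.7-fold and the imprinted Peg3 7.83-fold higher (n = 2 against 1). Hand1 had 264 reads against 2, a ratio of 54.8 (95% counting interval 15.0 to 454). Olig2, a glial and neural factor, stood at 3.61 log2 CPM in V6.5 and at -1.9 and -2.45 in the libraries labelled clone 1 and clone 2, with 120 reads against 1, a ratio of 289 (95% counting interval 50.9 to 11500.0), and Nr5a2 was 3.85-fold lower. Of 555 X-linked genes 398 were higher and 9 lower, with a median of 0.93. Dusp9 did not pass (0.79 ± 0.66, adjusted p = 0.392). Rps4x-ps, Rpl28-ps3 and Ftl2-ps, processed pseudogenes, and Tuba3b were listed at 0 reads in V6.5 and were among the largest increases. Chromosome 8 had a median deviation of 0.27 in V6.5 at 0 h from the mean of all withdrawal libraries. On it 49.5% of 735 genes were called against 32.9% on the other autosomes, 69 higher and 295 lower, with a median of -0.41. The clones and V6.5 differ in mouse strain as well as in sex and genotype, so these cannot be separated.

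**Figure D4:**
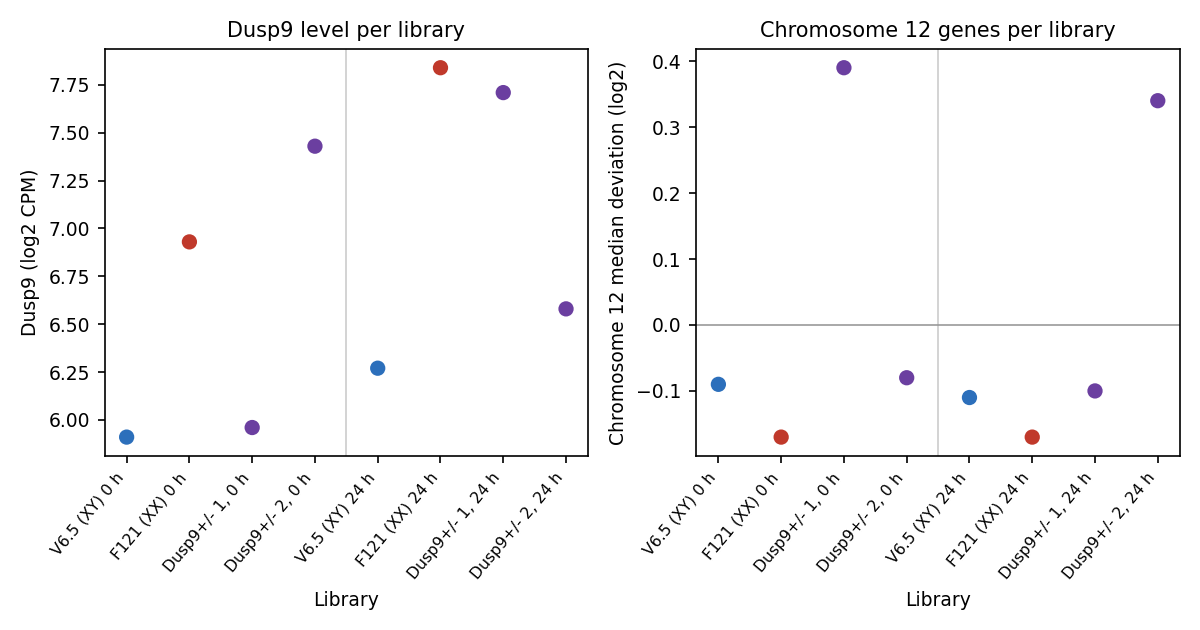
Dusp9 level in log2 CPM (left) and median deviation of chromosome 12 genes in log2 (right) for each of the 8 libraries of the LIF-withdrawal experiment (blue V6.5, red F121, purple Dusp9+/-), each point 1 library. Dusp9 is lower and chromosome 12 higher in the library labelled clone 1 at 0 h (5.96 and 0.39) and in the library labelled clone 2 at 24 h (6.58 and 0.34).

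LIF withdrawal for 24 h was compared with 0 h over the 4 lines to ask how naive cells leave their state. The immediate-early genes Fosb and Fos fell by 7.09 ± 0.32 and 5.41 ± 0.34 on the log2 scale, with Rgs1, a regulator of G-protein signals, 18.2-fold lower (-4.18 log2, with -0.88 at a pseudocount of 5 and -5.56 by voom, n = 4 against 4). Klf4 fell 6.46-fold, Tbx3 8.47-fold, Tfcp2l1 5.05-fold and the LIF target Socs3 6.43-fold. Among the largest increases were Bcl11a, a zinc-finger repressor (12.8-fold), the glutamate receptor Grm6 (11.3-fold), Vrtn, the vertnin gene (8.94-fold), the cyclin Ccno (8.49-fold) and the retinoid receptor Rxrg (6.4-fold). Dnmt3b rose 2.98-fold. In all 4688 of 14335 genes were called, 2410 higher and 2278 lower, with 101 X-linked genes higher and 62 lower.

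Of 22 naive genes 16 fell and 1 rose (17 and 2 adjusted over the list alone), including Tcl1 (-1.58 ± 0.11) and Nanog (-1.64 ± 0.15). Of 19 formative and primed genes 15 rose and none fell (15 adjusted over the list alone), with Sall2 (2.49 ± 0.26), Lef1 (1.91 ± 0.23) and Grhl2 (1.15 ± 0.1). Of 18 LIF and Stat3 targets 13 fell and 1 rose (the same counts adjusted over the list alone), with Stat3 itself at -1.34 ± 0.1. Core genes rose in 7 of 12 cases (7 higher and 2 lower adjusted over the list alone), such as Lin28a (0.63 ± 0.1). The ERK list had 5 of 22 higher and 3 lower (7 and 3 adjusted over the list alone), with Spry4 (1.27 ± 0.09) and Dusp6 (1.18 ± 0.13) up and Egr1 (-2.05 ± 0.34) down. Its median was 0.17 and its mean -0.08, and camera pointed up (adjusted p = 0.316). DNA methylation genes rose in 7 of 18 cases and fell in 2 (8 and 2 adjusted over the list alone). Hells, a chromatin remodeller, rose by 0.62 ± 0.07. Neuroectoderm genes rose in 3 of 9 cases and fell in 1 (3 and 1 adjusted over the list alone), with Sox1 at 1.56 ± 0.29. The interferon genes Usp18 and Irf7 were 17.1-fold and 16.1-fold lower, and 10 of 17 immediate-early and stress genes (11 lower and 1 higher adjusted over the list alone), 11 of 24 fibroblast genes (11 adjusted over the list alone) and 5 of 7 mitochondrially encoded genes (7 adjusted over the list alone) fell. The fibroblast mean fell from 6.01 to 4.61 in F121, from 6.09 to 4.28 in V6.5 and from 4.56 to 3.47 in the libraries labelled clone 2, but rose from 3.67 to 4.16 in those labelled clone 1. The Y-linked mean went from 2.03 to 0.5 in F121, from 0.76 to 0.39 under the label clone 1 and from 1.45 to -0.83 under the label clone 2. Camera called the naive, formative, LIF and core lists (adjusted p = 9.5e-07, 7.29e-07, 5.14e-07 and 0.0101), each with adjusted p = 0.366 with an estimated correlation. Without the library labelled Dusp9+/- clone 2 at 24 h the count was 3086.

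The 24 h response of the libraries labelled Dusp9+/- was set against that of WT XX. By limma 0 of 14335 genes passed, with 1766 at an unadjusted p under 0.05 and 0 by voom. The Xist difference in response was -1.69 ± 0.27 (adjusted p = 0.206). Adjusted over the list alone, 10 of 22 naive genes had a higher 24 h change in the libraries labelled Dusp9+/- than in WT XX, and 7 of 19 formative genes had a lower change and 2 a higher one. With an estimated correlation both lists had adjusted p = 0.766. The fibroblast list moved in the same direction as the naive one and further (median 1.0 against 0.48), and WT XX was 1 library at each time. The count became 1 without the library labelled clone 1 at 0 h and 24 without clone 2 at 0 h. For WT XX against WT XY, 1 line each, 0 genes passed by limma and 0 by voom. The 612 at an unadjusted p under 0.05 by limma were a share below the 0.05 that chance alone gives on average. The Xist value was 1.69 ± 0.31 (adjusted p = 0.752).

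Genes called in more than 1 comparison were counted where the compared groups shared no library. Between XX against XY iPSCs at P7 and WT XX against XY ESCs 239 genes were called in both, against 47.8 for independent lists, and all 239 had the same sign. Of the 1405 genes called in either, 86.8% had the same sign, and of all genes 63.0%. On autosomes 109 were shared against 28.0, and 78 of them were higher in XX in both. The female and male passage comparisons shared 541 genes against 164.1, with all signs alike, whereas 92.2% of genes called in either and 70.2% of all genes had the same sign. Both came from 1 fit with 1 spread per gene, which can itself raise the number shared. Among the shared genes Irf7, Ifit3, Col3a1 and Jun were named above. Autosomal genes called in XX against XY iPSCs and in the libraries labelled Dusp9+/- against WT XX at 0 h numbered 109 against 43.7, of which 103 had the opposite sign, while 20.3% of those called in either and 37.4% of all autosomal genes had the same sign. For the CM lines against the same comparison the number was 225 against 124.6, with 176 of opposite sign, and the same sign in 37.3% of those called in either and 46.9% of all autosomal genes. All pairs after the one between iPSCs and ESCs were chosen after the values were seen.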

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

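The list tests and their comparisons were planned. Of the tests of explanations and of other splits, only the one asking whether the library labelled LV16 at P13 was a P7 library was written before its result was seen, and the others were chosen after the results they measure were seen. Each list value below is a median log2 difference that passed camera with a preset correlation in a test of the difference itself, and none of them passed with an estimated correlation.

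The change from P7 to P13 differed between female and male iPSC lines for 10 gene lists. It was lower in the female lines for germline genes (-0.47), the X-inactivation centre (-0.44), X escape genes (-0.44), the X-linked hand list (-0.4), fibroblast and feeder genes (-0.45), p53 targets (-0.22), mitochondrially encoded genes (-0.58) and immediate-early and stress genes (-0.34). It was higher for Y-linked genes (1.26) and for glycolysis and hypoxia genes (0.37). With an estimated correlation the adjusted p ranged from 0.264 to 0.756.

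The 24 h change of the libraries labelled Dusp9+/- relative to WT XX was higher for naive (0.48), fibroblast (1.0) and trophoblast genes (0.97), and lower for formative and primed genes (-0.5), the X-inactivation centre (-0.59), mesendoderm (-0.67), glycolysis and hypoxia (-0.38) and immediate-early genes (-0.24). All 8 had an adjusted p of 0.766 with an estimated correlation. For WT XX relative to WT XY the 24 h change was higher for fibroblast (0.3), primitive endoderm (0.42), mesendoderm (0.68) and glycolysis genes (0.23), and lower for formative (-0.27), neuroectoderm (-0.5) and immediate-early genes (-0.47), with adjusted p from 0.731 to 0.788 with an estimated correlation.

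In XX iPSCs at P7 the X-linked output of LV21 (-0.16) lay below that of LV20 (0.44) and LV22 (0.58), and at P13 that of LV22 (-0.15) lay above that of LV20 (-0.53) and LV21 (-0.59). Male cells in LV21 at P7 are argued against, since 4 Y-linked genes stood at 2.86% of their level in XY libraries, within the 2.63 to 4.62% of the other XX libraries, where a share of 73.4% would be needed. A candidate explanation is that part of the cells of LV21 had already lost an X chromosome at P7, because the fall was 0.48 to 0.58 log2 in each of 4 parts of the X and 85.1% of 509 X-linked genes were lower than in the other XX libraries. For LV22 at P13, where XX cells may remain, the smallest rise over the same 4 parts was 0.29 and the largest 0.34, with 87.0% of genes higher, which lies just under the bound of 0.3 set for that test, so a mixture stays open. A lower output from both X chromosomes in LV21 was not tested.

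The libraries labelled Dusp9+/- clone 1 and clone 2 exchanged several of their differences between 0 h and 24 h: clone 1 minus clone 2 was -1.47 for Dusp9 at 0 h and 1.12 at 24 h. The chromosome 12 median of the same difference, over 385 genes, was 0.46 at 0 h and -0.45 at 24 h, whereas the other 18 autosomes reached at most 0.06 and 0.05. Unequal shares of feeder cells are argued against for chromosome 12, which stood at least 8.1 times beyond any other autosome at both times, but are a candidate explanation for the fibroblast list, which differed by -0.98 at 0 h and 0.74 at 24 h with Y-linked genes moving the same way by at least 0.69, and were not tested for Dusp9. Against that explanation stands that the labels describe this experiment as grown without feeder cells, and male feeders are named only for the chromatin samples. Clone numbers crossed at 1 of the times and a separate gain of chromosome 12 at each time cannot be told apart: the change of sign raised the former and so does not test it, and the clone differences at the 2 times correlated at -0.36 across genes outside chromosome 12 and the fibroblast list, short of the -0.5 set to tell them apart, while genes are not independent replicates.

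Interferon-response genes (15 genes, a list chosen after the values were seen) had a mean of 3.52 to 4.65 log2 CPM in 5 of the 6 P13 iPSC libraries and of 1.94 in LV16 at P13. Feeder cells as the source cannot be judged from the 7 other libraries with a fibroblast mean of at least 5.25. Of these 5 had a low interferon mean, down to 1.39. They are LV16 at P13, which the pattern concerns, and CM1, CM2, CM3 and CM7 from 1 separate experiment. F121 and V6.5 at 0 h, from another experiment, were high (4.36 and 4.03). A high fibroblast mean thus came without a high interferon mean in the CM lines, but feeders that differ between experiments were not tested. That LV16 at P13 was a P7 library is argued against, because over 1226 genes its change towards P13 was 0.32. This is 64.2% of that in LV4 (0.51) and LV8 (0.49), and the fibroblast mean of LV16 at P13 was 5.47. A difference in culture or handling between libraries was not tested, and no biological explanation was tested.

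Other splits of the same libraries were fitted for each count of called genes. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in XX against XY iPSCs at P7 (668, highest other 0), XO against XY at P13 (4, highest other 0), the female lines (1258, highest other 0), the male lines (1823, highest other 0) and WT ESCs (1020, highest other 0). For the interaction the real split and all others gave 0 genes, so 10 of 10 were as large. For 24 h against 0 h 1 of 34 splits, the real one, gave as many genes (4688, highest other 1), and 1 further split could not be estimated. That share ignores the lines. Of the 8 splits that part all 4 pairs of a line's libraries 1, the real one, was as large and the highest other was 0, and 8 splits are too few for a share under 0.05.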

How the results depend on the processing

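The pseudocount of 1, voom, the fit without LV21 at P7 and LV22 at P13 and the block with crossed clones were chosen after seeing the data, and the rest before. Of 253 alternative values of counts and X-linked medians 202 stayed within their bounds, 49 moved and 2 reversed. For counts the bound was a change of at most 1.5 times, and for X-linked medians only the sign was checked. Counts of 0 that stayed 0 are among the 202. Of 4083 for single named genes 3682 kept direction and side of the threshold, 382 lost it, 8 gained it and 11 reversed. Folds of low genes depend on the offset: a pseudocount of 5, which by construction shrinks them, moved 88 of the 223 called genes named by over 1.5 times and one of 0.1 moved 9. Except where a clause says otherwise, the cause was not tested.

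A fold minimum, which by construction keeps fewer genes, gave 247 for XX against XY iPSCs at P7 (668 as reported), 440 for the female passage comparison (1258), 676 for the male one (1823), 383 for WT ESCs (1020), 689 for the libraries labelled Dusp9+/- against WT XX at 0 h (1277), 2445 against WT XY (4992) and 1218 for 24 h against 0 h (4688). The spread of the compared libraries alone gave 428 for XX against XY at P7 and 436 for the female lines, but 2329 for the male lines, within the bound. The line as a block gave 11 for the interaction (0 as reported) and changed no other count by over 1.5 times, with the crossed block also within that range. Without LV21 at P7 and LV22 at P13 XX against XY at P7 gave 1818 and the interaction 364. In WT ESCs no term for the experiment gave 149 and the CM lines alone 1690. No filter gave 759 at 0 h and 0 at 24 h for the libraries labelled Dusp9+/- against WT XX (366 as reported at 24 h). At 24 h a pseudocount of 5 gave 178, quantile normalization 148 and voom 16. The additive model estimates 1 genotype difference over both times. It gave the same 1904 for 0 h and 24 h, which is not a value for either time. Of 104 gene list calls 2 held with an estimated correlation. The share of one sign in the overlap of iPSCs and ESCs was 100% over genes called in both and 86.8% over those called in either.

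Leaving out 1 library gave counts of 44 to 1727 for XX against XY at P7, 4 in each case for XO against XY at P13, 174 to 2079 for the female and 429 to 2198 for the male lines, 0 to 145 for the interaction, 208 to 1682 for WT ESCs, 1610 to 1953 for the libraries labelled Dusp9+/- at 0 h, 1 to 104 at 24 h, 5136 to 5328 against WT XY, 3086 to 4158 for 24 h against 0 h and 0 to 24 for the difference in response. In comparisons of the libraries labelled Dusp9+/- with WT, this left 1 library against 1. The spread then came from the clones at the other time alone. The X-linked difference ran from 0.65 to 1.02 for XX against XY at P7 (0.79), from -0.1 to 0.12 for XO against XY (0.04), from -0.93 to -0.56 for the female lines (-0.71), from 0.01 to 0.09 for the male lines (0.05) and from 0.68 to 0.84 for WT ESCs (0.78). It reversed for XO against XY, to -0.1, without LV22 at P13 and without both LV21 at P7 and LV22 at P13. Among uncalled genes Xist in XO against XY became -0.06 under the same 2 alternatives (range -0.06 to 1.65 with 1 library left out). Dusp9 at 0 h became 0.5 without clone 1 (-0.97 to 0.5), and its difference in response 0.28 and 0.1 without clone 2 at 0 h and 24 h (-1.19 to 0.28). Kdm5d in WT ESCs (-0.35 to 0.3) became 0.01 after centring, 0.3 without CM7, 0.02 without CM2 and 0.05 without F121, without V6.5 and in the CM lines alone. The fits without F121 and without V6.5 also take sex from the CM lines alone.

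Not run were leaving out the lone F121 or V6.5 library in the fits of genotype and time, the line as a random block for the differences in response, and the technical repeats as separate libraries, since the table has 1 column for each line and time. A gene with 0 reads in a library can have an expected count of up to 3 reads at the 95% level, so differences below that were not detectable.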

Other observations

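The mean of genes of the interferon response was 1.15 to 1.83 log2 CPM at P7 and 3.52 to 4.65 at P13 in 5 of the 6 iPSC lines, and 1.66 at P7 and 1.94 at P13 in LV16. On a list of 15 such genes, chosen after their values were seen, 11 rose from P7 to P13 in the female lines (median 2.13) and 6 in the male lines (median 1.7), none fell in either, and 14 fell from 0 h to 24 h of LIF withdrawal (median -2.66). The interferon mean was 1.39 to 1.74 log2 CPM in the CM lines, 3.95 to 4.36 in the withdrawal libraries at 0 h and 0.82 to 2.47 at 24 h.

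Whole chromosomes stood apart in 6 library values, beyond 0.25 log2. Each value is a median deviation from the mean of all libraries of the same experiment, the library itself included, less that library's autosomal median. Chromosome 8 was higher in LV21 at P7 (0.29, with 89.1% of 589 genes above) and at P13 (0.42, with 92.5%), and in V6.5 at 0 h (0.27, with 75.2% of 588 genes) and 24 h (0.35, with 78.4%). Chromosome 12 was higher in the library labelled Dusp9+/- clone 1 at 0 h (0.39, with 89.1% of 385 genes) and in the library labelled clone 2 at 24 h (0.34, with 88.3%). The other 226 values of the iPSC libraries lay between -0.14 and 0.06, the 148 of the withdrawal libraries between -0.18 and 0.18 and the 76 of the CM lines between -0.03 and 0.03.

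Residual values of the same line at P7 and P13 correlated across genes at 0.03 in LV20, 0.09 in LV21, 0.1 in LV22, 0.07 in LV4, 0.11 in LV8 and -0.04 in LV16, and at -0.36 for the libraries labelled clone 1 and clone 2 between 0 h and 24 h. Genes are not independent replicates, and no test was run on these values.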
